A study of Mus musculus with 2 samples.

How the data were processed

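Brains of Sox10:Cre RCE+ mice at postnatal day 21 were dissociated and sorted on GFP, and single-cell libraries were made with droplet 3' chemistry. There were 2 libraries of 1 group. Part of the labels names both GFP-positive and GFP-negative sorting and part names GFP-positive cells alone, without saying which fraction a library holds. Nothing in the labels says that the libraries came from separate animals, so no p-value can be taken to cover the spread between animals. With library as a block, the gene tests rest on how differences between classes varied between these 2 samples. Per the submitters' processing notes, reads were counted with Cell Ranger 3.0.2 on mm10. The deposited matrices hold UMI counts per gene and barcode with no normalisation, for 31053 genes and the GFP sequence, as written by the authors' counting. The authors also deposited a cell table of 13 columns. UMI counts, GFP counts, library and class were read from it. Its gene counts, mitochondrial percent, embedding, cluster numbers and 4 further columns entered no result. Its UMI counts per cell are raw, and its mitochondrial percent values were made by the authors as percent of a cell's UMIs without GFP. The authors' UMI totals equalled sums over the matrices, without GFP and without genes seen in fewer than 3 barcodes of a library, except in 2 cells that differed by 1 UMI. The annotated cells were exactly the barcodes with at least 6 GFP UMIs and under 15% mitochondrial UMIs.

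The libraries were compared first. They shared 13 barcodes, and a chi-square of their summed counts over its degrees of freedom was 26.0, so they were not one library deposited a second time. Library 1 held 42885780 UMIs in 8203 barcodes and library 2 held 48141294 in 5644. Annotated barcodes had a median of 6975 and 7338 UMIs, and the others 1819 and 3701. Intervals and floors cover counting error only. A gene at 0 in a group was given a fold change against a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with a 95% Poisson interval. Shares of cells were given 95% exact Clopper-Pearson intervals.

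UMIs were summed per authors' class and library, which gave 16 profiles. The smallest were OPC, with 415997 UMIs from 42 cells and 462743 from 46. The largest were Oligodendrocytes, with 10803347 and 18376674. Genes were tested with the edgeR 4.0.16 quasi-likelihood F test (R 4.3.3, limma 3.58.1), with TMM factors, filterByExpr, robust estimation, library as replicate block and 7 residual degrees of freedom. All 8 classes were fitted together, and p-values were adjusted by Benjamini-Hochberg over the 12796 genes that passed the filter. A gene was called at an adjusted p under 0.05. Normalised CPM are CPM with TMM factors, and raw CPM are UMIs scaled to the total of a profile. Errors of fold changes are standard errors of the fitted coefficient. Values for a single library used a prior count of 2, which pulls large fold changes towards 0. The classes were made by the authors from the same expression values, so p-values between classes are optimistic. A repeat in which classes came from one part of each cell's UMIs and the test from the remaining part was an alternative, and 96.5% of cells were given their class in it. That share was 76.2% and 87.0% for OPC and 84.9% and 59.6% for OEC in libraries 1 and 2, and above 92% for the other classes.

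The comparisons, the 18 gene lists, the cell type markers, the alternatives and the rule for named genes were chosen before the data were examined. By that rule the text may name the 5 genes with the largest called change in each direction that moved the same way in both libraries and reached 50 CPM. From each list it may name up to 4 called members with at least 20 CPM and up to 2 members not called, and 15 lineage genes and the cell type markers may be named anywhere. Genes that were named for the OPC class beside its markers, among them Dlx1, Cd24a, Dcx and Cenpf, were chosen after their values were seen. Some genes that the rule allows are not reported here. Of 10 planned comparisons 2 were not run, because the annotation joins committed precursors with newly formed oligodendrocytes and divides mature cells no further. Lists were tested with camera (preset correlation 0.01) and fry, adjusted over the lists of a comparison. Of the camera calls, those that held with an estimated correlation were progenitor transcription factors, S phase and proteoglycans in Oligodendrocytes against OPC, S phase in COP-NFOL against OPC, and antigen presentation in OEC and in VEC against the lineage. With total counts as well, S phase in COP-NFOL against OPC and antigen presentation in OEC held.

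Barcodes were named from markers alone by multinomial likelihood. Seed barcodes had at least 4 markers of a type and led the next list by 0.2 of its markers, a type needed 20 seeds, and profiles were refined in 4 rounds. The profile of progenitor-named barcodes was led by the ciliary genes Tmem212 and Ccdc153 beside Top2a and C1ql1, so that name is less pure than the others, and unannotated barcodes with it are not reported. In simulated cells of 1000 UMIs drawn from the named profiles, 100% of 1100 received their own name. The same profiles made and scored these cells, so this does not show that real barcodes were named correctly. Doublets were scored with scrublet in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). It marked 0 of 8203 barcodes in library 1 with its automatic threshold of 0.518, which is no usable call for a library of that size, and 96 of 5644 (1.70%) in library 2. Removing the highest scores at an assumed rate of 0.8% per 1000 barcodes (538 and 255 barcodes) and keeping only cells whose marker-based name was their class were alternatives chosen after seeing the data. Shares of barcodes with a UMI were computed after thinning each barcode to 2000 UMIs, with shallower barcodes left out. Plots were drawn with matplotlib 3.10.9.

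The other alternatives were DESeq2 1.42.0, size factors of its type, total counts only, no filter, no replicate block, removal of scrublet doublets, an equal number of cells per class (42 and 46), and each library alone. With no filter the estimated prior degrees of freedom were infinite for all 21230 genes (median 8.72 in the main analysis). A gene's own spread then did not enter its p-value, although the deviance of Opalin, for one, was 7.20 per degree of freedom. The p-values without a filter are therefore too small, and ranges of adjusted p in the text cover the other 9 alternatives, a choice made after seeing the data. The tests were tried on simulated counts with 200 changed genes per comparison. In Oligodendrocytes against OPC, 83.0% of 4-fold and 8.0% of 2-fold changes were recovered, with 0 false calls among 91. Far fewer genes were changed there than were called in the data, so neither rate carries over to the comparisons. Gene positions came from GENCODE M21 for mm10. Unannotated barcodes entered no comparison.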

Results

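Messenger RNA was counted in single cells from the brains of mice at postnatal day 21 that carried a Sox10:Cre transgene and the RCE reporter. In such mice a cell that once expressed Cre, and all of its descendants, can make green fluorescent protein (GFP), and cells sorted on GFP were captured in 2 droplet libraries. Both libraries belonged to 1 group, so the only comparisons were between cell classes, and the only replication was between the libraries. Library 1 held 8203 barcodes with 42885780 unique molecular identifiers (UMIs) in total and a median of 3068 per barcode. Library 2 held 5644 barcodes with 48141294 UMIs and a median of 5445.5. The authors assigned 2511 barcodes of library 1 (30.6%) and 2977 of library 2 (52.7%) to 8 cell classes. These annotated barcodes were exactly those with at least 6 GFP UMIs and less than 15% mitochondrial UMIs. Across 12796 genes, the summed profiles of a class in both libraries correlated with Spearman's rho from 0.924 in OPC to 0.995 in Oligodendrocytes. Genes are not independent replicates, so no p-value was attached to these correlations.

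The classes were 3 stages of the oligodendrocyte lineage and 5 classes outside it. The stages were oligodendrocyte progenitors (OPC), a joint class of committed precursors and newly formed oligodendrocytes (COP-NFOL), and Oligodendrocytes. The others were Astrocytes, olfactory ensheathing cells (OEC), Pericytes, vascular endothelial cells (VEC) and vascular leptomeningeal cells (VLMC). Astrocytes made up 47.6% ± 5.62 of the annotated barcodes (mean and SD, n = 2 libraries) and Oligodendrocytes 21.4% ± 5.60. Pericytes made up 7.71% ± 0.311, COP-NFOL 4.31% ± 0.514, VLMC 2.78% ± 0.156, VEC 2.30% ± 0.122 and OPC 1.61% ± 0.0901. The OEC share differed most between the libraries. It was 20.8% in library 1 (95% exact binomial interval 19.2 to 22.4) and 3.83% in library 2 (3.17 to 4.58). These shares describe sorting and droplet recovery, and 2 libraries of 1 group allowed no test between groups.

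**Figure D1:**
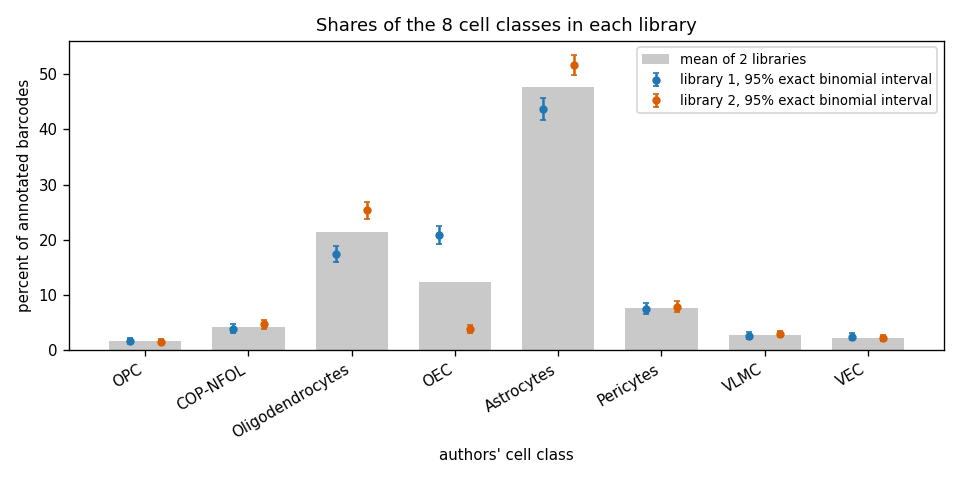
Share of each authors' cell class (x axis) among the annotated barcodes (y axis, percent). Bars are the mean of both libraries and points the libraries with their 95% exact binomial intervals; OEC make up 20.8% of library 1 and 3.83% of library 2.

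The GFP gate held cells with Sox10 transcript and cells almost without it. Sox10 encodes the transcription factor whose regulatory sequence drove Cre. It is ENSMUSG00000033006, on chromosome 15 from 79154908 to 79165240 of mm10. Sox10 reached 562 ± 31.8 raw CPM in COP-NFOL (UMIs scaled to the total of the profile, mean and SD, n = 2 libraries), 358 ± 20.8 in Oligodendrocytes, 264 ± 48.9 in OEC and 255 ± 82.1 in OPC. The order of OEC and OPC differed between the libraries, with 299 and 197 in library 1 and 229 and 313 in library 2. Sox10 stayed at 9.29 ± 9.003 in Pericytes, 8.62 ± 5.78 in VEC, 7.03 ± 0.272 in Astrocytes and 6.52 ± 0.794 in VLMC. GFP itself showed another order. Within the gate of 6 GFP UMIs its transcript was highest in Pericytes, at 4428 ± 469 raw CPM, followed by VLMC at 2928 ± 124 and Astrocytes at 2468 ± 41.2. It was 1656 ± 80.7 in COP-NFOL, 1546 ± 10.6 in OPC, 1499.9 ± 146 in VEC and 1422 ± 104.7 in OEC, and lowest in Oligodendrocytes at 566 ± 26.7. The order of VEC and OEC differed between the libraries, and marker-named barcodes without the gate had 1075 ± 61.4 in VEC and 1369 ± 207 in OEC. CPM are relative to depth, and the median depth was 3915 UMIs in Pericytes and 24411 in Oligodendrocytes (means of both libraries). Per cell, COP-NFOL had the most GFP, at 30.7 ± 0.307 UMIs, before VLMC at 23.8 ± 2.30 and Pericytes at 19.4 ± 1.84. Oligodendrocytes were lowest at 13.9 ± 0.515, near OEC at 15.2 ± 4.58. With gated barcodes thinned to 2000 UMIs, Pericytes were highest at 9.22 ± 0.526 and Oligodendrocytes lowest at 1.10 ± 0.0291. With each barcode thinned to 2000 UMIs, 64.2% ± 7.41 of COP-NFOL barcodes and 50.7% ± 0.0974 of Oligodendrocytes still had a Sox10 UMI. The share was 36.1% ± 2.25 in OEC and 33.7% ± 10.7 in OPC. It was 2.63% ± 3.72 in VEC, 1.43% ± 0.0289 in Astrocytes, 1.38% ± 0.300 in VLMC and 1.35% ± 0.624 in Pericytes. Barcodes named as microglia by markers, a type that should lack Sox10, had 2.25% ± 1.17 at that depth, so the share in these 4 classes was read as background. Before thinning, the median depth was 5868 UMIs in Astrocytes and 4378.5 in microglia-named barcodes (means of both libraries).

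**Figure D2:**
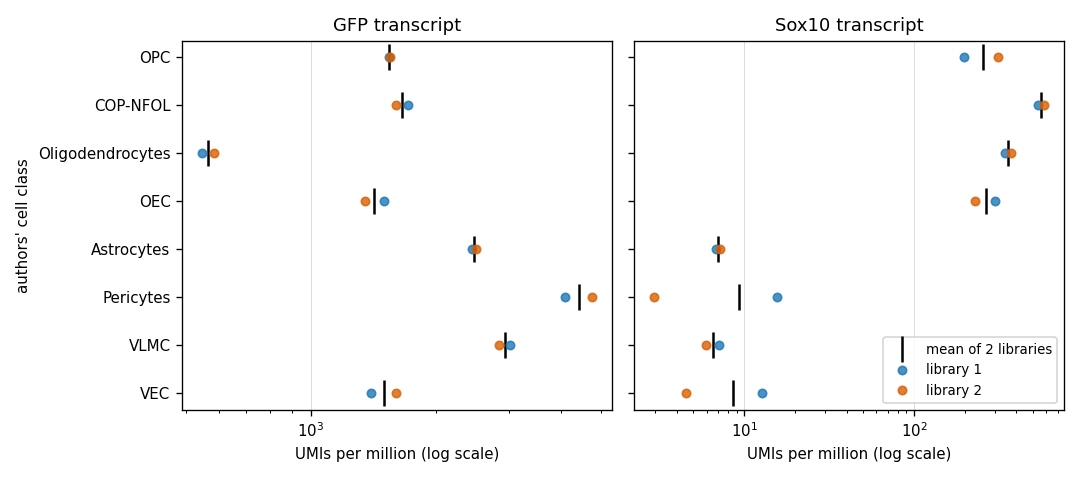
GFP and Sox10 transcripts (x axes, raw CPM, that is UMIs scaled to the total of the profile, log scale) in the 8 authors' cell classes (y axis). Points are the 2 libraries and bars their mean; mean Sox10 lies between 255 and 562 in OPC, COP-NFOL, Oligodendrocytes and OEC and at 9.29 or less in the other 4 classes, while mean GFP is lowest in Oligodendrocytes.

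Marker lists written before the data were examined set the classes apart. Pericyte and smooth muscle markers, with Vtn and Rgs5 the most abundant, summed to 32592 raw CPM in Pericytes. Endothelial markers such as Cldn5 and Itm2a summed to 16531 in VEC, astrocyte markers such as Slc1a2 and Aldoc to 15824 in Astrocytes, and VLMC markers such as Dcn and Col1a2 to 12585 in VLMC. The OEC markers Npy, Fabp7 and Frzb led a list that summed to 21615 in the OEC of library 1 and 8847 in those of library 2. Other lists were not confined to 1 class. Mature oligodendrocyte markers summed to 32398 in Oligodendrocytes but to 37487 in VLMC, where Ptgds alone gave 26224 raw CPM in library 1 and 29435 in library 2. They summed to 13868 in OEC. The OEC class also carried 4661 of astrocyte markers. Its microglia and macrophage markers summed to 1514 in library 1 and 4037 in library 2, and its erythrocyte markers to 249.6 and 4867. Barcodes were also named from markers alone. The authors' class and that name were the same for all 1191 Oligodendrocytes, for 2615 of 2632 Astrocytes (99.4%), for 148 of 153 VLMC (96.7%) and for 406 of 424 Pericytes (95.8%). They were the same for 218 of 238 COP-NFOL barcodes (91.6%), 115 of 126 VEC (91.3%), 55 of 88 OPC (62.5%) and 394 of 636 OEC (61.9%). In libraries 1 and 2 this share was 47.6% and 76.1% for OPC and 66.1% and 43.0% for OEC. Of the remaining OEC barcodes, 95 were named oligodendrocytes, 75 astrocytes, 34 microglia and 25 neurons.

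**Figure D3:**
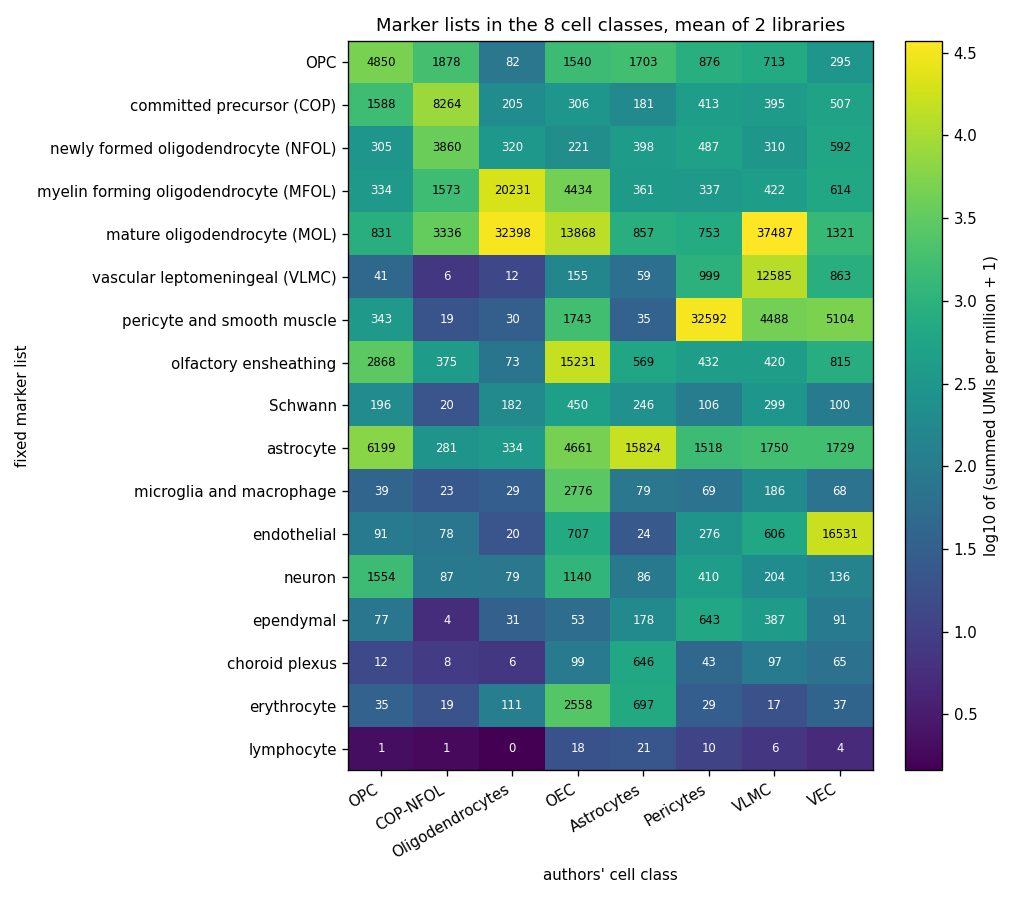
Summed markers of each cell type (y axis) in each authors' cell class (x axis), as raw CPM averaged over both libraries (colour, log scale). Among the classes, OEC, astrocyte, pericyte, endothelial and VLMC lists peak in their own class, whereas the mature oligodendrocyte list gives 37487 in VLMC against 32398 in Oligodendrocytes.

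The OPC class was small and mixed, with 42 barcodes in library 1 and 46 in library 2, and this bears on every comparison with it. Astrocyte markers summed to 6199 raw CPM in it, OPC markers such as Pdgfra and Vcan to 4850.4 and neuron markers to 1554. Of its 88 barcodes, 19 were named astrocytes and 10 neurons. Dlx1 and Dlx2, transcription factors of forebrain interneuron precursors, were detected in 24 of them. None of the 24 (0%) had a UMI of the progenitor genes Pdgfra or Cspg4, against 65.6% of the other 64. The 24 barcodes held 96.0% of the class's Cd24a UMIs, 85.9% of Sox11 and 80.7% of Dcx. They held 30.8% of Top2a and 25.4% of Cenpf, both genes of cell division. The 42 barcodes with Pdgfra or Cspg4 held 54.2% of Top2a and 58.3% of Cenpf.

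The first step out of the progenitor state was read from COP-NFOL against OPC. Enpp6, a phosphodiesterase of newly formed oligodendrocytes, was 621-fold higher in COP-NFOL (95% counting interval 212 to 3010), with 3 UMIs in OPC. Bmp4, a signalling ligand of committed precursors, rose from 15.9 to 879.8 normalised CPM, a log2 fold change of 5.79 ± 0.38 (SE, n = 2 libraries, adjusted p = 1.09e-07). Tcf7l2, an effector of Wnt signalling, rose by 3.89 ± 0.20 (adjusted p = 1.88e-09) and the receptor Gpr17 by 3.06 ± 0.35 (adjusted p = 3.29e-05). Pdgfra, the receptor that keeps progenitors dividing, fell by 6.93 ± 0.54 (adjusted p = 1.64e-06; fell by 5.78 in library 1 alone), and Cspg4 fell by 3.11 ± 0.32. Of 20 measured myelin components, 16 rose and 0 fell (17 rose adjusted over the list alone). Mbp rose by 6.61 ± 0.41 to 5484 CPM and Nfasc by 5.38 ± 0.38. Opalin, a late myelin gene, rose by 3.85 ± 0.98 (adjusted p = 0.0123), but with equal numbers of cells per class its adjusted p was 0.136 (5.04e-05 to 0.136 over 9 alternatives). Of 23 cholesterol synthesis genes 22 rose, with Hmgcs1 up by 2.41 ± 0.31 and Mvd by 2.27 ± 0.23, while Srebf2 was not called (0.23 ± 0.20, adjusted p = 0.415). Differentiation transcription factors rose in 13 of 16 cases and fell in 0, led by Myrf at 5.53 ± 0.62 and Zfp365 at 4.57 ± 0.37. Sox10 rose by 1.46 ± 0.27 (adjusted p = 0.00101). Olig2 rose by 0.58 ± 0.20 (adjusted p = 0.0382), but by 0.02 (adjusted p = 0.945; 4.46e-06 to 0.945 over 9 alternatives, called in 3) when only barcodes whose marker name was their class were used, and Olig1 was not called (-0.18 ± 0.36, adjusted p = 0.76; 3.35e-07 to 0.833 over 9 alternatives, called in 1). Of 50 genes of the G2 and M phases 47 fell and 0 rose. Top2a was at least 723-fold and Cenpf at least 441-fold lower in COP-NFOL. Progenitor transcription factors fell in 13 of 18 cases and rose in 2 (14 and 0 with total counts), with Etv5 at -5.86 ± 0.39. Camera gave the lists adjusted p-values of 6.98e-10 for myelin, 4.5e-09 for cholesterol and 4.77e-22 for G2 and M, which became 0.14, 0.131 and 0.0807 with an estimated correlation. Differentiation and progenitor factors had 4.04e-05 and 4.11e-06, and 0.0807 each with an estimated correlation. Adjusted over the list alone, 14 differentiation factors rose and 14 progenitor factors fell, with the cholesterol and G2 and M counts unchanged. Cd24a was at least 169-fold lower, and most of its UMIs in the OPC class came from the 24 barcodes with Dlx1 or Dlx2. In total 4484 of 12796 genes were called, 2175 higher (48.5%) and 2309 lower. Scaling by total counts alone moved the median log2 fold change of all genes to -0.31 and the higher share to 27.7%.

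The step to mature cells was read from Oligodendrocytes against COP-NFOL. Bmp4 fell by 8.37 ± 0.34 (log2, SE, n = 2 libraries, adjusted p = 4.42e-10), Gpr17 fell by 5.73 ± 0.36 (adjusted p = 1.08e-07) and Tcf7l2 fell by 4.83 ± 0.18 (adjusted p = 2.41e-11), from 831 to 29.1 CPM. Enpp6 fell by 2.77 ± 0.22, from 1732 to 254 CPM. Late myelin genes rose. Ermn gained 4.84 ± 0.48, Mal 4.70 ± 0.42, the gap junction gene Gjb1 4.68 ± 0.39 and Opalin 4.35 ± 0.52 (adjusted p = 7.44e-05). In all, 18 of 20 myelin components rose and 1 fell, and the counts of this list and of the others named here were the same when adjusted over the list alone. Mbp, which encodes the basic protein that compacts myelin, was not called (0.44 ± 0.30, adjusted p = 0.272; 0.0034 to 0.959 over 9 alternatives, called in 1). Mog rose by 3.22 ± 0.48 and Mag by 2.28 ± 0.41, but with equal numbers of cells per class their adjusted p-values were 0.0574 and 0.183. These were the highest of 9 alternatives, and the lowest were 5.38e-14 and 1.51e-15. The camera p-value of the list was 2.19e-08, against 0.333 with an estimated correlation. Cholesterol synthesis was not called as a list (camera adjusted p = 0.682), and its median log2 fold change of 0.06 became -0.35 with total counts. In it 5 of 23 genes fell (10 with total counts) and 2 rose, such as Sc5d at 1.10 ± 0.20. The mature group 5 and 6 marker list rose in 11 of 14 cases and fell in 2 (camera adjusted p = 0.000394, and 0.328 with an estimated correlation), with Anln at 5.13 ± 0.27 (5.84 in library 1 alone). Iron handling genes rose in 6 of 14 cases and fell in 1 (camera adjusted p = 0.0058, and 0.328 with an estimated correlation). The iron store gene Fth1 rose by 3.74 ± 0.21 to 23014 CPM, the transferrin gene Trf by 4.32 ± 0.50 and the heme transporter Slc48a1 by 3.33 ± 0.26. The carbonic anhydrase Car2 rose by 4.53 ± 0.42 and the lactate transporter Slc16a1 by 2.89 ± 0.27. Proteoglycans fell in 8 of 16 cases and rose in 2 (camera adjusted p = 0.0169, 0.333 with an estimated correlation and 0.0671 with total counts), with Tnr at -8.34 ± 0.44 and Vcan at -7.82 ± 0.36. Among transcription factors Sox6 fell by 7.25 ± 0.37, Sox4 by 4.60 ± 0.21 and Olig2 by 1.08 ± 0.19, and Nkx6-2 rose by 2.96 ± 0.28. Myrf was not called (0.65 ± 0.28, adjusted p = 0.0884), but was called higher in 4 of 9 alternatives (3.93e-06 to 0.552). Sox10 was not called either (-0.25 ± 0.24, adjusted p = 0.459), although it was called lower with total counts (-0.65, adjusted p = 0.0384; 0.0308 to 0.675 over 9 alternatives, called in 2). The test called 5493 genes, 2828 higher (51.5%) and 2665 lower. Total-count scaling moved the median of all genes to -0.33 and the higher share to 26.8%.

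**Figure D4:**
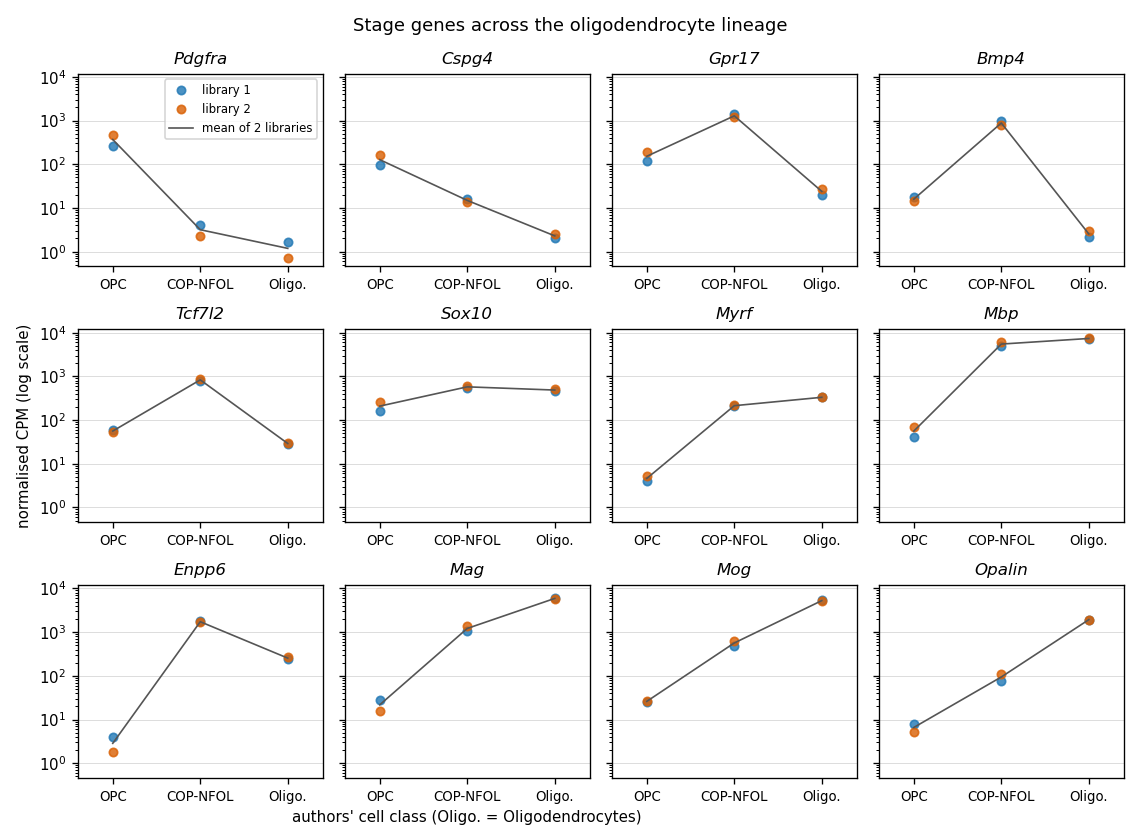
Normalised CPM (y axis, log scale) of 12 stage genes in OPC, COP-NFOL and Oligodendrocytes (x axis). Points are the 2 libraries and lines join their means; Enpp6, Gpr17, Bmp4 and Tcf7l2 are highest in COP-NFOL, with means of 1732, 1284, 879.8 and 831 CPM.

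Across the whole path, Oligodendrocytes against OPC, Mag rose by 8.10 ± 0.61 (log2, SE, n = 2 libraries, adjusted p = 1.47e-06), Opalin by 8.20 ± 0.81 (adjusted p = 1.62e-05) and Mbp by 7.05 ± 0.42 (adjusted p = 7.98e-08). Pdgfra fell by 8.37 ± 0.50 (adjusted p = 6.96e-08; fell by 6.84 in library 1 alone) and Cspg4 fell by 5.76 ± 0.33 (adjusted p = 4.2e-09; fell by 5.17 in library 1 alone). All 20 measured myelin components rose (camera adjusted p = 6.58e-14, and 0.107 with an estimated correlation). So did 22 of 23 cholesterol genes, with Acat2 not called (0.23 ± 0.26, adjusted p = 0.511). With total counts 12 of the 23 rose, and their median log2 fold change went from 1.35 to 0.61. Also higher were 12 of 14 galactolipid and sphingolipid genes, among them Fa2h at 5.79 ± 0.55 and Ugt8a at 5.45 ± 0.48. Cholesterol and galactolipid lists had camera adjusted p-values of 1.09e-06 and 3.45e-06, against 0.18 and 0.0944 with an estimated correlation. All 18 progenitor transcription factors fell, with Sox11 at -9.29 ± 0.27 (-8.68 in library 2 alone) and Sox6 at -6.25 ± 0.40 (-5.40 in library 1 alone). With only barcodes whose marker name was their class, 15 of 18 fell and 0 rose, and the counts were the same with equal numbers of cells per class. In Astrocytes against the lineage 14 of these factors were higher and 1 lower, and 19 of 88 OPC barcodes were named astrocytes. Most Sox11 UMIs of the OPC class came from the barcodes with Dlx1 or Dlx2. Proteoglycans fell in 14 of 16 cases and rose in 1, and S phase genes fell in 33 of 38 and rose in 1. The proteoglycan, S phase and progenitor factor lists held with an estimated correlation (adjusted p = 0.0376 each), but not with an estimated correlation and total counts (0.0705 each). The S phase gene Pcna was not called (-0.05 ± 0.25, adjusted p = 0.896), but fell by 0.78 with total counts (adjusted p = 0.0192; 0.0192 to 0.983 over 9 alternatives). Of 50 genes of the G2 and M phases 46 fell and 1 rose (camera adjusted p = 2.81e-16, and 0.0944 with an estimated correlation). Kif23 was at least 442-fold lower in Oligodendrocytes, and Top2a 3581-fold lower (1225 to 17362) from 3 UMIs. Glutamate and GABA receptors fell in 19 of 26 cases and rose in 3 (camera adjusted p = 7.13e-05, and 0.1 with an estimated correlation). Cacng4, an auxiliary protein of AMPA receptors, fell by 7.48 ± 0.40. Myrf rose by 6.17 ± 0.59 and Sox10 by 1.21 ± 0.27 (adjusted p = 0.0021), though Sox10 was at 0.48 (adjusted p = 0.149; 2.5e-09 to 0.149 over 9 alternatives) with total counts. Olig1 (0.64 ± 0.36, adjusted p = 0.173; 0.000103 to 0.863 over 9 alternatives, called in 1) and Olig2 (-0.51 ± 0.20, adjusted p = 0.0504) were not called; Olig2 was called lower in 7 of 9 alternatives, whose adjusted p-values ran from 9.56e-10 to 0.141. Adjusted over the list alone, counts were the same for these lists except that 2 genes of the G2 and M phases rose. In total 6178 genes were called, 3003 higher (48.6%) and 3175 lower. Total-count scaling moved the median of all genes to -0.72 and the higher share to 18.7%, and DESeq2 moved them to -0.19 and 40.3%.

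**Figure D5:**
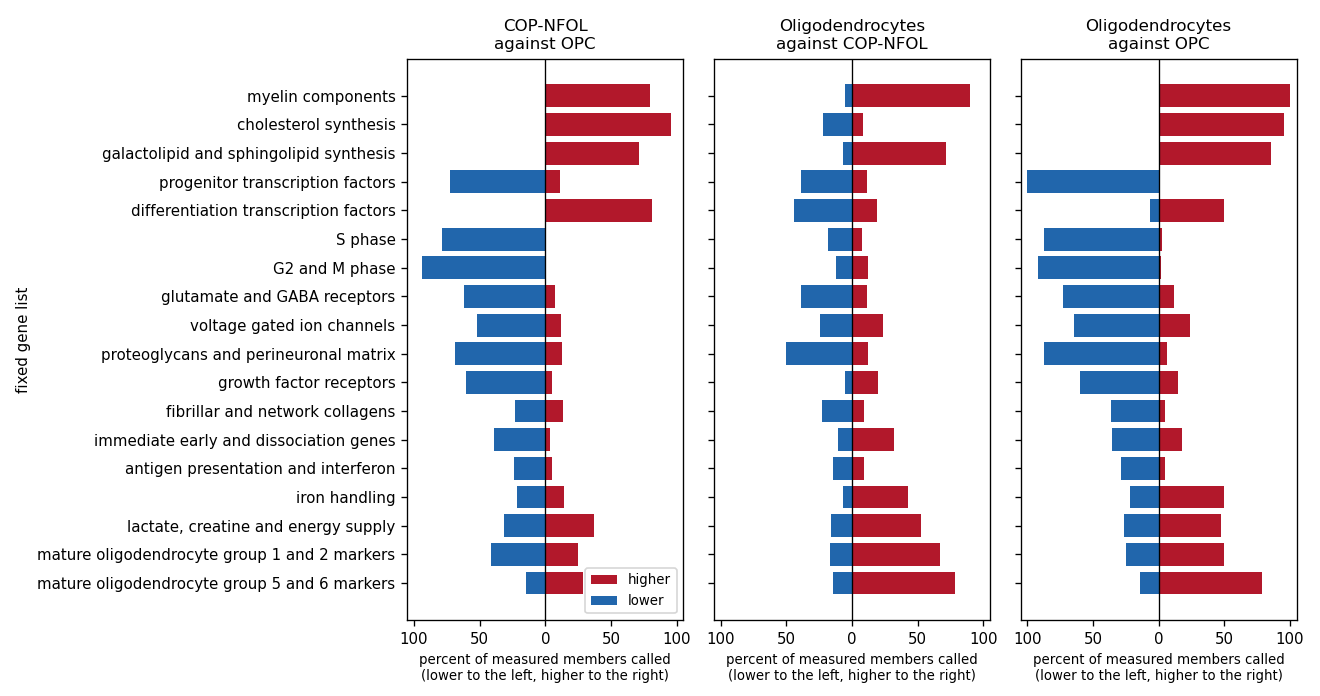
Share of measured members called (x axes, percent, lower to the left and higher to the right) for the 18 fixed gene lists (y axis) in the 3 comparisons within the lineage. Cholesterol synthesis rises in 22 of 23 genes from OPC to COP-NFOL and in 2 from COP-NFOL to Oligodendrocytes, whereas myelin components rise in 16 and then 18 of 20.

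Each class outside the lineage was set against the mean of the 3 stages to describe what else the gate held. The mean was taken on the log scale, so a gene confined to 1 stage can have a fold change smaller than its arithmetic means show. In Astrocytes Sox10 fell by 5.62 ± 0.30 (log2, SE, n = 2 libraries, adjusted p = 2.66e-09), Gpr17 by 5.43 ± 0.39 and Mbp by 3.56 ± 0.32. Igfbp2, which encodes a binding protein of insulin-like growth factors, rose by 5.86 ± 0.20 (adjusted p = 2.21e-11), from 15.1 to 612 CPM. Mgat4c rose by 6.06 ± 0.21 (5.10 in library 2 alone). Of 18 progenitor transcription factors 14 were higher in Astrocytes and 1 lower, among them Hes5 at 4.95 ± 0.39, Id2 at 4.77 ± 0.22 and Sox9, a glial factor, at 4.33 ± 0.27. Growth factor receptors were higher in 13 of 20 cases and lower in 3, with Fgfr3, a known astrocyte receptor, at 4.76 ± 0.18. Antigen presentation and interferon genes were higher in 16 of 21 cases and lower in 0, with Tap2 at 3.70 ± 0.20 and C4b at 2.78 ± 0.19. Apoe, the lipid carrier of astrocytes, reached 26342.5 CPM against 2526, a rise of 4.40 ± 0.27. Myelin components were lower in 17 of 20 cases and higher in 2. Adjusted over the list alone, 17 antigen presentation genes and 14 receptors were higher and 18 myelin genes lower. Cholesterol synthesis went both ways, with 7 genes higher and 8 lower (camera adjusted p = 0.648), and Msmo1 rose by 1.28 ± 0.13. The camera p-values of these 4 moving lists were 0.000123 for progenitor factors, 0.00161 for receptors, 2.63e-05 for antigen presentation and 1.03e-06 for myelin. With an estimated correlation the first 3 were 0.168 and myelin 0.267. Ttr, a choroid plexus gene, rose by 6.42 ± 0.39, but by 0.76 (adjusted p = 0.332; 5.5e-22 to 0.332 over 9 alternatives) when only barcodes named astrocytes by markers were used. The test called 7923 genes, 4365 higher (55.1%) and 3558 lower.

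OEC are glia of the olfactory nerve that express Sox10 outside the oligodendrocyte lineage. Sox10 was not called (-0.54 ± 0.21, adjusted p = 0.0533; 0.0503 to 0.84 over 9 alternatives), while Olig2 fell by 2.84 ± 0.20 (SE, n = 2 libraries, adjusted p = 3.26e-08) and Gpr17 by 4.24 ± 0.39 (-3.56 in library 1 and -5.89 in library 2 alone). Apoe rose by 4.58 ± 0.27 to 30920.2 CPM and the Notch target Hes5 by 4.80 ± 0.39. Fibrillar and network collagens were higher in 17 of 22 cases and lower in 1 (camera adjusted p = 2.93e-05, and 0.156 with an estimated correlation), with Col5a2 at 5.51 ± 0.43. Growth factor receptors were higher in 15 of 20 cases and lower in 1 (0.000258, and 0.156 with an estimated correlation), with Fgfr1 at 2.39 ± 0.17. Antigen presentation and interferon genes were higher in 20 of 21 cases, and this list held with an estimated correlation (camera adjusted p = 3.5e-12, and 0.0264), with Ifitm3 at 5.75 ± 0.25. Cholesterol synthesis was lower in 14 of 23 cases and higher in 0 (0.000226, and 0.313 with an estimated correlation), with Acat2 at -1.52 ± 0.20. Immediate early and dissociation genes were higher in 17 of 28 cases and lower in 2 (0.000463, and 0.295 with an estimated correlation). Counts adjusted over the list alone were the same for these 5 lists. With only barcodes named OEC or their own stage, immediate early and dissociation genes were higher in 9 of 27 cases and lower in 5. Collagens and receptors were then higher in 12 of 20 cases each, and lower in 1 and 2. Antigen presentation genes were higher in all 20, and cholesterol genes lower in 16 of 23 and higher in 1. Mbp was not called (-0.17 ± 0.26, adjusted p = 0.636). With only barcodes named OEC by markers, Mbp was at -3.37 (adjusted p = 2.83e-17). Mbp was called in 3 of 9 alternatives, whose adjusted p-values ran from 2.83e-17 to 0.982. The 5 genes with the largest rise were of microglia, namely Fcer1g (9.35 ± 0.74), Csf1r, Ly86, Gpr34 and Laptm5 (8.66 ± 0.49), and none of the 5 passed the count filter once only barcodes named OEC were used. The test called 5823 genes, 3412 higher (58.6%) and 2411 lower. With only barcodes named OEC or their own stage, 76.5% of these calls were kept. Total-count scaling moved the median of all genes to 0.11 and the higher share to 62.9%.

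In Pericytes Art3 rose by 12.22 ± 0.27 (log2, SE, n = 2 libraries, adjusted p = 9.49e-14; 9.20 in library 1 and 9.39 in library 2 alone). Pdgfrb, the receptor that recruits mural cells, rose by 8.05 ± 0.25 (adjusted p = 5.7e-11; 8.66 in library 1 alone) from 10.6 to 1979.8 CPM. Cspg4, shared by pericytes and progenitors, rose by 5.33 ± 0.18 to 657 CPM, and Hes1 by 5.11 ± 0.28. Collagens were higher in 13 of 22 cases and lower in 2, with Col4a2 of the basement membrane at 7.70 ± 0.28. Antigen presentation and interferon genes were higher in 16 of 21 cases and lower in 0. Of 23 cholesterol genes 22 fell, with Cyp51 at -3.42 ± 0.27 and Hmgcs1 at -3.38 ± 0.31, and myelin components fell in 18 of 20 cases. Camera adjusted p-values were 0.000331, 4.71e-06, 1.08e-09 and 2.18e-08 for these 4 lists, and 0.221, 0.152, 0.221 and 0.251 with an estimated correlation. Adjusted over the list alone, 14 collagens and 17 antigen presentation genes were higher, and 23 cholesterol genes and 20 myelin components lower. Immediate early and dissociation genes were higher in 15 of 28 cases and lower in 4, or 16 and 4 adjusted over the list alone (0.00844, and 0.417 with an estimated correlation). Sox10 fell by 5.57 ± 0.38 (adjusted p = 4.47e-08; -4.54 in library 1 and -6.97 in library 2 alone). The ferroxidase Cp rose by 6.88 ± 0.18. The test called 6335 genes, 3259 higher (51.4%) and 3076 lower, and total-count scaling moved the median of all genes to 0.15 and the higher share to 60.9%.

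In VEC Klf2, induced by blood flow, rose by 9.11 ± 0.24 (log2, SE, n = 2 libraries, adjusted p = 3.9e-13) to 1157 CPM and Klf4 by 7.77 ± 0.27. Sox17 rose by 10.39 ± 0.37 (8.40 in library 1 and 8.26 in library 2 alone), and Id1 by 6.46 ± 0.31. The iron exporter Slc40a1 rose by 8.45 ± 0.31 (7.44 in library 1 alone) and the transferrin receptor Tfrc by 3.79 ± 0.18. Antigen presentation and interferon genes were higher in 18 of 21 cases and lower in 0 (19 higher adjusted over the list alone), and the list held with an estimated correlation (camera adjusted p = 4.83e-10, and 0.0496), though not with total counts as well (0.0796). Ifitm3 rose by 7.47 ± 0.25. Immediate early and dissociation genes were higher in 21 of 28 cases and lower in 2, or 22 and 3 adjusted over the list alone (3.95e-05, and 0.274 with an estimated correlation). All 23 cholesterol genes fell, with Hmgcs1 at -3.28 ± 0.31 (3.04e-10, and 0.274 with an estimated correlation). Sox10 fell by 5.58 ± 0.41 (adjusted p = 1.02e-07; -4.79 in library 1 and -6.44 in library 2 alone). The test called 5885 genes, 3229 higher (54.9%) and 2656 lower, and total-count scaling moved the median of all genes to 0.13 and the higher share to 63.1%.

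In VLMC Col3a1, a fibrillar collagen, rose by 11.86 ± 0.29 (log2, SE, n = 2 libraries, adjusted p = 1.43e-12; 9.60 in library 1 and 10.79 in library 2 alone), from 0.727 to 1262 CPM. Coch was 13370-fold higher (95% counting interval 2399.7 to 528099), from 1 UMI in the lineage. This ratio used the lineage profiles pooled, with most of their UMIs from Oligodendrocytes. The log2 fold changes here were instead taken against the mean of the stages, so the ratio cannot be compared with them directly. Collagens were higher in 19 of 22 cases and lower in 2, the same counts adjusted over the list alone (camera adjusted p = 3.66e-08, and 0.0771 with an estimated correlation). Ptgds, a prostaglandin synthase secreted by meninges, rose by 5.34 ± 0.40 to 26054 CPM. Pdgfra, which the meningeal class shared with progenitors, rose by 5.62 ± 0.31, to 512 CPM, and Cp rose by 8.59 ± 0.16. Antigen presentation and interferon genes were higher in 18 of 21 cases and lower in 0 (1.74e-08, and 0.0721 with an estimated correlation). Immediate early and dissociation genes were higher in 18 of 28 cases and lower in 2 (0.000252, and 0.235 with an estimated correlation), with Cyr61 at 7.27 ± 0.37 (6.11 in library 1 alone). Cholesterol synthesis fell in 20 of 23 cases (21 adjusted over the list alone), with Hmgcs1 at -2.38 ± 0.29 (2.95e-07, and 0.195 with an estimated correlation). Sox10 fell by 5.99 ± 0.43 (adjusted p = 1.05e-07) and Mbp by 3.90 ± 0.35. The test called 5858 genes, 3141 higher (53.6%) and 2717 lower, and total-count scaling moved the median of all genes to 0.12 and the higher share to 62.7%.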

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

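The tests of GFP without Sox10, of sequencing depth behind the OEC shares, of doublets of microglia and OEC and of free Dlx1 and Dlx2 RNA were chosen only after the result was seen; the bounds of the others were written before their values were computed. The labels hold 1 group of samples, so no biological explanation was tested for any pattern.

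Astrocytes, Pericytes, VEC and VLMC carried GFP with a mean of 9.29 raw CPM of Sox10 or less (at most 15.7 in 1 library). Free GFP RNA shared by all droplets would give all types a like level. Before any gate VEC-named barcodes, the lowest of the 4, had 2.92 times the GFP of microglia-named ones (2.78 and 3.05 in the libraries). Neuron-named barcodes lay nearer, with 738 and 616 raw CPM in libraries 1 and 2 against 1032 and 1119 in VEC-named ones. The values therefore argue against free RNA for Astrocytes, Pericytes and VLMC, whose named barcodes had 1960, 4190 and 2755 (means of both libraries). For VEC, whose named profile was led by Ttr, free RNA stays open. Oligodendrocyte-named barcodes had 531 and 534 raw CPM in libraries 1 and 2, below the neuron-named ones, although their class carried Sox10. A level near that of neuron-named barcodes thus does not by itself show free RNA. Doublets with oligodendrocyte lineage cells would bring Sox10, which reached 1.70% of the COP-NFOL level in the highest of the 4 classes (2.90 in the library where it was higher). At 2000 UMIs and with no gate VEC-named barcodes, again the lowest, had 3.02 times the GFP of microglia-named ones (2.76 and 3.29). In libraries 1 and 2 their mean was 1.88 and 1.92 GFP UMIs, against 1.34 and 1.24 in neuron-named barcodes. Astrocyte-named ones, the next lowest of the 4, had 3.71 and 3.90. The gate and depth thus argue no better for Astrocytes, Pericytes and VLMC, but stay open for VEC. What remains may be past Cre expression in ancestors of these cells or Cre activity without Sox10, and these stay open as well.

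Genes of microglia led the OEC class. Microglia-named barcodes were 34 of its 636 (5.35%), or 3.45% of the class in library 1 and 14.0% in library 2. They held 61.5% of the UMIs of Fcer1g, Ly86, Gpr34, Laptm5 and C1qc (95% interval over resampled barcodes 52.6 to 70.8). This lay between the bounds of 80 and 20 set beforehand, so cells of that type may explain the larger part while the rest stays open. Oligodendrocyte-named barcodes of the class held another 20.5%, astrocyte-named ones 10.7% and OEC-named ones 1.54%. The values argue against doublets of a microglial cell and an OEC, since OEC markers, weighted by the UMIs of the 5 genes over all barcodes of the class, lay at 2.25% (1.55 to 3.27) of the level in barcodes without such a UMI, but other doublets stay open, since scrublet marked 21 of 114 OEC barcodes in library 2 (18.4%, against 4.55% in VEC, the next highest class). A difference in depth was weighed for the unequal OEC shares. Their ratio between libraries was 5.43 among all annotated cells. Among cells with at least 2000 UMIs it was 5.32 (4.10 to 6.96, from the ends of the exact intervals). That cut kept 495 of 522 OEC in library 1 and 113 of 114 in library 2. It removed too few cells to move the ratio much and left the GFP gate in place, so that cut cannot decide the question. Named by markers with no gate, under the mitochondrial limit, OEC were 1031 of 8203 barcodes in library 1 and 81 of 5644 in library 2. Of these, 632 and 69 were deep enough for thinning to 2000 UMIs. The gate passed 34.0% of those named in library 1 and 63.0% in library 2. For marker-named barcodes these values argue against depth and the gate as the source of the gap.

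Dlx1 and Dlx2 appeared in 24 of 88 barcodes of the OPC class. The share of barcodes with a Pdgfra or Cspg4 UMI was 0 times that of the other barcodes (0% against 65.6%, at medians of 9206.5 and 9326.5 UMIs), which is consistent with cells of another type in the class, such as interneuron precursors. Doublets with a progenitor would carry its markers, which reached 12.4% of the level in the other barcodes (upper end of the 95% interval over resampled barcodes 18.5). Free RNA would reach all classes, but Dlx1 and Dlx2 stood at 1.94% of the OPC level in Astrocytes, the highest of the other 7 classes.

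Barcodes that entered no comparison were counted as well. Of 8359 unannotated barcodes 6581 (78.7%) had at least 1 GFP UMI, 3221 of them named astrocytes, and 1778 had 0. At least 1 UMI does not by itself show expression, since 66.6% and 61.9% of unannotated microglia-named barcodes had one in library 1 and 2. A further count, within these, was 445 barcodes with at least 6 GFP UMIs but at least 15% mitochondrial UMIs, 359 of them named astrocytes and 46 OEC. Under that mitochondrial limit, 710 unannotated barcodes were named OEC, 680 in library 1 and 30 in library 2. They held 16995.5 raw CPM of Fabp7, 6349.8 of Npy and 399.6 of Sox10, with a median of 1659.5 UMIs and 2 GFP UMIs.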

How the results depend on the processing

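The removal of the highest scrublet scores at an assumed rate and the restriction to cells whose marker-based name was their class were chosen after seeing the data; the other alternatives were planned. Of 120 named gene results, 109 were called, and none of their 1434 alternative values reversed a call. DESeq2 left direction and call the same for 118, DESeq2-type size factors for 118, total counts for 112, scrublet doublets removed for 118, the assumed doublet rate for 117 and the held-out UMIs for 114. With only marker-matched cells this held for 107 of 115, and with equal cells per class for 113 of 119. No filter left 114 the same, but its p-values ignore each gene's own spread, so this says nothing about the stability of single calls. The tests were also run with no replicate block, where 119 of 120 named genes were the same and 6176 genes were called in Oligodendrocytes against OPC. Folds in 1 library alone have no test, since no residual degrees of freedom remain. Of the 120, 4 had another sign in 1 library, and 0 of those 4 had been called. The rule named leading genes only if they were called and moved the same way in both libraries, so this agreement was partly fixed in advance. Without replicate 1, 41 of 120 folds differed from the main one in sign or by more than the SD between the libraries. Without replicate 2 the number was also 41. A main fold midway between the folds of both libraries can never differ from them by that SD. Single-library folds were also pulled towards 0 by their prior count, and the SD is small where the libraries are alike. These numbers therefore do not measure disagreement between the libraries.

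Counts of called genes stayed within 1.5 times the main count except with equal cells per class. There 4084 genes were called in Oligodendrocytes against OPC, 2900 in COP-NFOL against OPC, 2910 in Oligodendrocytes against COP-NFOL, 3289 in Astrocytes, 2201 in OEC, 3276 in Pericytes and 3847 in VLMC. Fewer cells and fewer genes past the filter (10078) give less power, and 36.4% of the main calls were kept in OEC and 67.6% in VEC. Camera with an estimated correlation called 3 lists in Oligodendrocytes against OPC, 1 in COP-NFOL against OPC, 0 in Oligodendrocytes against COP-NFOL, 0 in Astrocytes, 1 in OEC, 0 in Pericytes, 1 in VEC and 0 in VLMC. Estimated correlations above 0.01 widen the test by construction. Of 18 lists, fry called 16 in Oligodendrocytes against OPC, 14 in COP-NFOL against OPC and 9 in Oligodendrocytes against COP-NFOL. It called 13 in Astrocytes, 15 in OEC, 18 in Pericytes, 15 in VEC and 15 in VLMC. Fry does not set a list against the other genes, so its counts answer another question than those of camera.

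Among cells with at least 2000 UMIs the Pericyte share was 7.15%, with 385 of 424 Pericytes left by construction; the other 7 shares moved by less than 1 SD. Thinned to 2000 UMIs, neuron markers in OPC summed to 2014 raw CPM, mature oligodendrocyte markers in Oligodendrocytes to 32824, astrocyte markers in Astrocytes to 15381, endothelial markers in VEC to 17405 and VLMC markers in VLMC to 13443; the cause was not tested. Over all 21230 genes with a count, Spearman's rho was 0.937 in OPC, 0.960 in COP-NFOL, 0.973 in Oligodendrocytes, 0.978 in Astrocytes, 0.953 in OEC, 0.954 in Pericytes and 0.945 in VEC; the cause was not tested.

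The alternatives of both planned comparisons that the annotation does not allow were not run. The OPC profiles held the fewest UMIs, 415997 and 462743, but depth was not told apart from the mixed make-up of that class.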
